A study of Homo sapiens with 8 samples.

How the data were processed

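RNA was measured by sequencing in 8 resected peritoneal metastases from 8 patients. By the sample titles, 4 carried the label LAMN and came from low-grade appendiceal malignancies, and 4 carried the label CRC and came from adenocarcinoma. The tissue was homogenised and total RNA was extracted with Trizol, per the labels' protocols. The library kit, the removal of ribosomal RNA, the strand setting of the counting step and any sequencing batch were not given in the sources used here.

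The authors deposited a table of whole-number read counts per gene, with 1 column per library. Reads were trimmed with Trimmomatic, examined with FastQC, aligned with STAR to GRCh38.p13 and counted with featureCounts, per the submitters' processing notes, which name these tools with no version. Their notes also name DESeq2. The authors' deposited table of a LAMN against adenocarcinoma comparison gives, per the file headers, a mean of normalized counts, a log2 fold change with its standard error, a test statistic (a score) and a p-value with its adjusted p-value for 620 genes. The largest adjusted p in that table was 0.0500, so it holds only genes past the usual threshold. Its headers do not say which group was the reference.

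The count table held 62696 rows, of which 62131 were used. The 565 rows left out were those of XIST, TSIX and the Y chromosome, and library totals are given without them. Each count column was matched to a sample by its name, and 0 columns of per-sample values stayed unmatched. Positions and strands were taken from GENCODE v29 on GRCh38 for the 56170 used rows that it holds. A row was called an opposite-strand partner of a gene where their exons overlapped by at least 50 bp on opposite strands.

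Counts were tested with edgeR 4.0.16 in R 4.3.3, using trimmed mean of M-values (TMM) factors, filterByExpr at its defaults, a robust quasi-likelihood fit and the coefficient LAMN minus CRC. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM values were scaled by the TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. An estimated correlation and fry were the alternatives. Library measures were compared with two-sided exact permutation tests over the 70 arrangements of 8 libraries into 4 and 4, whose smallest p is 0.0286, adjusted over 14 measures. Principal components used the 500 most variable tested genes. The share of gene pairs has a 95% Clopper-Pearson interval, which covers counting of pairs only. Genes with 1 to 3 counts in a group also have a log2 ratio of their counts over the summed effective library sizes, with a 95% Clopper-Pearson interval that covers counting error and not the spread between libraries.

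The design, the 42 gene lists (682 distinct genes of metabolism, signalling, epithelium, stroma and other cell types), the rule for named genes and the alternatives listed below were fixed before the data were examined. The rule took the 8 largest changes in each direction past the threshold with a mean CPM of at least 5 and no overlap between the groups. Because 0 genes fell, its fallback applied, which names the 8 genes of each direction with the smallest p and says which did not pass. For each list described, members were named from among the 4 tested ones with the smallest p. Genes of the strand and deposited-table accounts were chosen after their values were seen. The alternatives were DESeq2 1.42.0, limma voom without and with quality weights, other scaling factors, other count filters, a fit that was not robust, the replicate number as a block, an epithelial covariate, other thresholds and leaving out each library in turn. Leaving out the mitochondrial ribosomal RNA rows, leaving out LAMN replicates 2 and 3 together, and testing opposite-strand rows in place of list members were added after the data were seen.

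The functions were tested on simulated counts drawn from the real means, library sizes and dispersions of the 9194 tested genes. Of these, 200 genes with a mean CPM of at least 5 were changed between 4 and 4 libraries. The share called among genes of lower CPM was not measured. edgeR called 0% of the genes changed by a log2 fold of 1, 20% at 2, 66% at 3 and 92% at 4, with 50 genes at each size. It also called 4 of the 8994 unchanged genes. DESeq2 called 52% at a log2 fold of 2 and 24 unchanged genes.

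Library totals ran from 1839750 to 6877302 counts. Without the mitochondrial ribosomal RNA rows, 380504 to 2290590 counts remained per library, so low-count genes were measured with little precision in the LAMN libraries. Rows that stand for HLA genes were left out of the values per library. Each library was another patient, so equal replicate numbers did not pair libraries.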

Results

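The data comprised 8 RNA-seq libraries of resected peritoneal metastases, the tumour deposits that abdominal cancers leave on the lining of the abdomen. There were 4 libraries labelled LAMN, from low-grade appendiceal mucinous neoplasms, which are slowly growing, mucus-producing tumours. The other 4 were labelled CRC and came from adenocarcinoma. Each library was from another patient. The LAMN libraries held 4390615 to 6877302 counts and the CRC libraries 1839750 to 2344418. The series compared the 2 kinds of metastasis with attention to metabolic pathways, as its title states.

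The rows of the mitochondrial ribosomal RNAs held far more counts in the libraries labelled LAMN than in those labelled CRC. MT-RNR1, the RNA of the small mitochondrial ribosomal subunit (chromosome M, 648 to 1601), was higher by 8.92 ± 1.00 (SE) on the log2 scale, with an edgeR adjusted p of 0.00869. MT-RNR2, the RNA of the large subunit (chromosome M, 1671 to 3229), was higher by 8.54 ± 1.00 (SE), with an edgeR adjusted p of 0.00949. Together they took 82.4% ± 11.9 of the counts in LAMN libraries and 1.69% ± 0.801 in CRC libraries (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0444). The LAMN shares ran from 69.2% to 93.5%, and the CRC shares from 0.717% to 2.39%. Mitochondrial ribosomal RNA stands in this text for the counts of both rows, which may lie opposite to the RNA counted. ENSG00000289474 and ENSG00000289901, which have no symbol in the files, were higher by 8.57 ± 0.804 and 9.52 ± 1.03 (SE), with edgeR adjusted p of 0.00451 and 0.00869. All 4 genes were higher in every LAMN library than in any CRC library.

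These 4 were the only genes past the threshold among 9194 tested with edgeR, and 0 genes were lower in LAMN libraries. At an unadjusted p under 0.05, 140 genes were higher and 223 lower, 363 in all against 459.7 expected by chance. DESeq2 called 6 genes, 5 higher and 1 lower, and limma voom called the same 4 genes. The 2 groups did not overlap for 264 genes, or 2.87% of those tested, where chance gives 2.86%. The number of genes called fell to 2 without CRC replicate 1, to 2 without CRC replicate 2, to 1 without CRC replicate 3, and to 2 when the fit was not robust. MT-RNR1 and MT-RNR2 were among the genes that lost the call in each of these settings, with adjusted p of 0.115 and 0.133, 0.0591 and 0.0632, 0.0561 for both, and 0.111 and 0.195. Their log2 fold changes stayed at 8.41 to 9.24 and 7.93 to 8.87 when any single library was left out. With library sizes as the only scaling, which the ribosomal RNA inflates in LAMN libraries, the median log2 fold change of all genes moved by -2.45 and 4 genes were higher and 7289 lower.

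**Figure D1:**
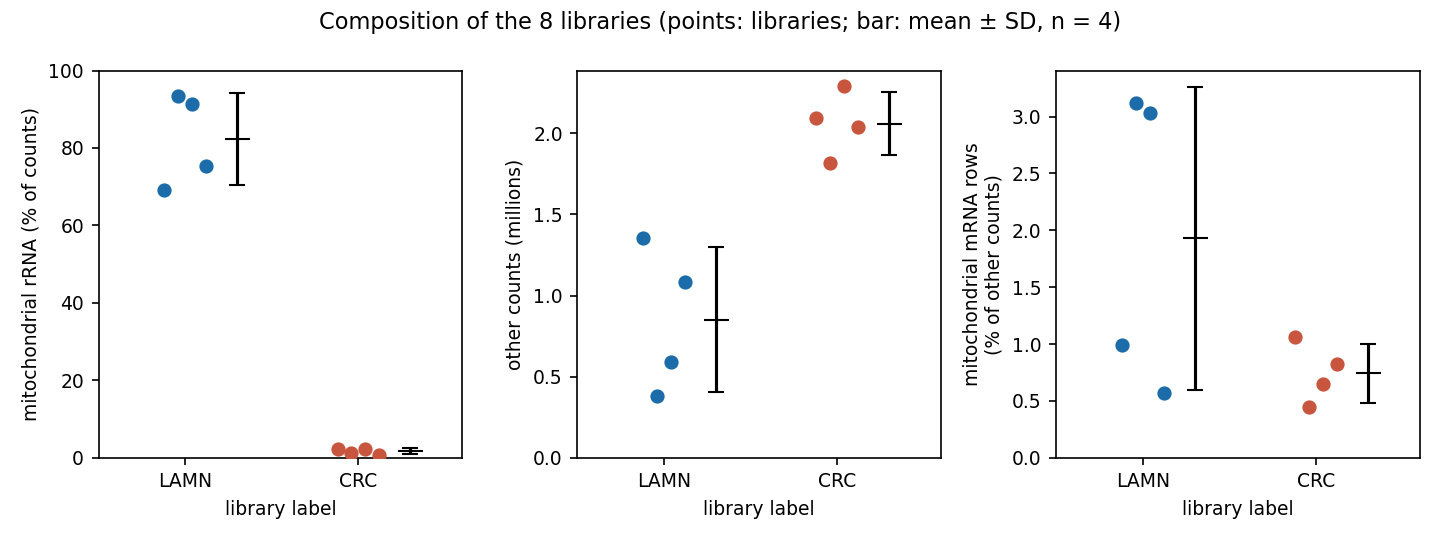
Share of counts in the mitochondrial ribosomal RNA rows (percent), counts in all other rows and share of the 13 mitochondrial mRNA rows among those other counts (percent), with 1 point per library and the mean ± SD of 4 libraries per label. The rows of mitochondrial ribosomal RNA held between 69.2% and 93.5% of the counts in LAMN libraries and between 0.717% and 2.39% in CRC libraries.

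The next genes by p did not pass the threshold, and their edgeR adjusted p lay between 0.444 and 0.997. On the higher side in LAMN libraries they were ENSG00000261654 at 3.05 ± 0.732, ENSG00000291075 at 2.14 ± 0.520, CHL1-AS1 at 2.61 ± 0.685 and OLFML1 at 1.99 ± 0.548 (log2 fold change ± SE). CHL1-AS1 lies opposite to the cell adhesion gene CHL1, and OLFML1 encodes a secreted olfactomedin-like protein. On the lower side the row of PPIE, a spliceosomal peptidyl-prolyl isomerase, had -4.37 ± 0.814 and the row of SIPA1, a GTPase-activating protein, had -4.33 ± 0.896. C16orf86 had -3.78 ± 0.727, the glutamate receptor gene GRIN2B -2.76 ± 0.602, ENSG00000238279 -2.63 ± 0.515 and SLCO4A1-AS1 -1.95 ± 0.449. NAV2-AS2 had -1.82 ± 0.443 and SCMH1, a Polycomb group gene, -1.81 ± 0.409. PPIE, SIPA1 and C16orf86 had only 2, 1 and 3 counts in LAMN libraries against 107, 58 and 96. Their log2 ratios of counts were -4.58, -4.70 and -3.84 (95% Clopper-Pearson intervals -7.64 to -2.69, -10.03 to -2.16 and -6.14 to -2.25). ENSG00000238279 passed with DESeq2 (adjusted p = 0.0157). OLFML1 and ENSG00000291075 changed sign, to -0.36 and -0.16, with library sizes as the only scaling.

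The genes of the respiratory chain that the mitochondrion itself encodes had higher values in LAMN libraries as a group. All 13 tested members lay above 0, with a median log2 fold change of 1.57, from 0.92 for MT-ND5 to 2.35 for MT-ATP8. MT-ATP6, a subunit of ATP synthase, had 1.81 ± 0.596 (SE), and the complex I subunits MT-ND3, MT-ND4L and MT-ND1 had 1.59 ± 0.567, 1.41 ± 0.521 and 2.19 ± 0.808. MT-ND1 had 0.66 without LAMN replicate 2. Over all genes tested 0 of the 13 passed with edgeR, 11 had an unadjusted p under 0.05, and 10 passed when adjusted over the list alone. The camera test with the preset correlation gave an adjusted p of 2.73e-10. With an estimated correlation the adjusted p was 0.705, and fry gave an adjusted p of 0.626. The share of these rows among counts other than mitochondrial ribosomal RNA was 3.12% in LAMN replicate 2 and 3.03% in LAMN replicate 3, and 0.573% and 0.995% in the other LAMN libraries. The CRC libraries held 0.743% ± 0.260 (SD, n = 4; exact permutation p = 0.200). Without LAMN replicates 2 and 3, chosen after seeing the data for their low remaining depth, the median was 0.16 and the camera adjusted p 0.750. With library sizes as the only scaling the median was -1.54 where that of all genes was -2.48, and camera still placed the list higher (adjusted p = 5.55e-05).

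**Figure D2:**
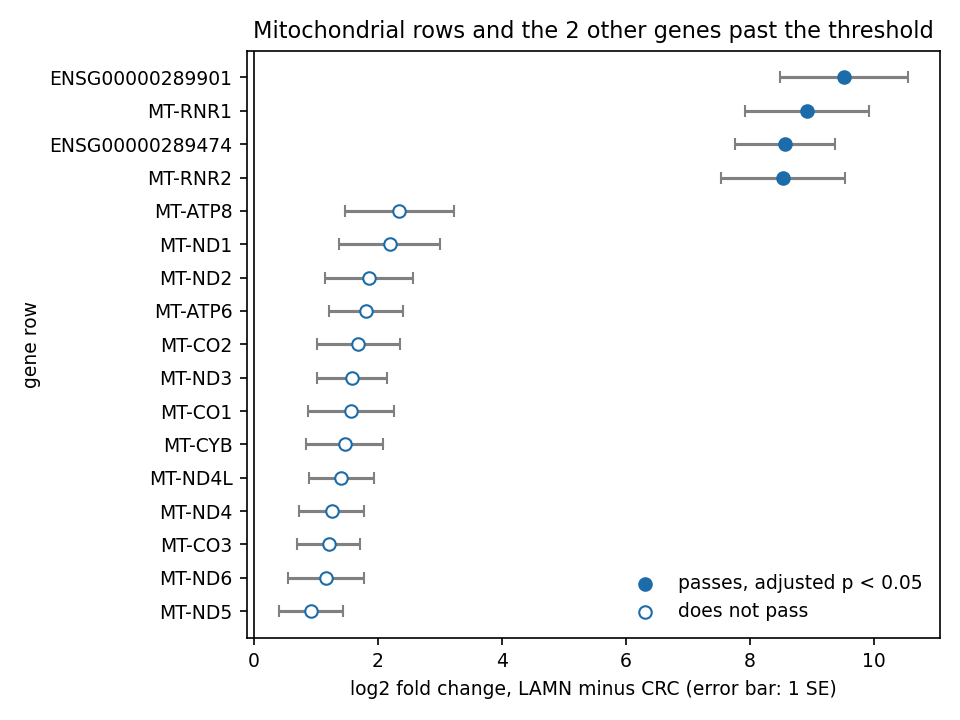
Log2 fold change, LAMN minus CRC, of the mitochondrial ribosomal and messenger RNA rows and of the 2 unnamed genes past the threshold, with bars of 1 SE (edgeR, 4 libraries per label). The 4 filled points lie at 8.54 or above and the 13 mRNA rows, none past the threshold over all genes, lie between 0.92 and 2.35; with library sizes as the only scaling the median of the 13 was -1.54 and that of all genes -2.48.

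No nuclear gene of the metabolic lists passed the test. Of all 682 listed genes, 154 had enough counts to be tested and 0 passed over all genes with edgeR, DESeq2 or limma voom. At an unadjusted p under 0.05, 17 of the 154 were found, 13 higher and 4 lower, and 11 of the 13 were the mitochondrially encoded genes. Of the 141 nuclear genes tested, 2 were higher and 4 lower at that level. Of the 113 list genes that the naming rule gave, 99 had a log2 fold change that moved by over 1.5 times when some single library was left out, so the values below describe these libraries only. They are values of gene rows, which need not give the abundance of the gene's own transcript, as the account of strands below sets out. In glycolysis 5 of 19 genes were tested, with a median log2 fold change of 0.20 (camera adjusted p = 0.413). GAPDH had 1.15 ± 0.498 (SE), the hexokinase HK2 -1.83 ± 0.840, the phosphofructokinase PFKM 0.74 ± 0.414 and the lactate transporter SLC16A3 0.20 ± 0.507. In glutamine metabolism 5 of 13 were tested (median 0.35, camera adjusted p = 0.413), and the glutamine transporter SLC1A5 had 1.26 ± 0.653 and GLUD1, a glutamate dehydrogenase, -0.88 ± 0.575. In fatty acid oxidation 5 of 24 were tested (median -0.23, camera adjusted p = 0.413, fry unadjusted p = 0.0426), with ACSL1 at -1.57 ± 1.02. In nucleotide synthesis 5 of 19 were tested (median 0.20, camera adjusted p = 0.413), with PPAT at 1.01 ± 0.873. In serine and one-carbon metabolism 6 of 14 were tested (median -0.18, camera adjusted p = 0.972), with the thymidylate synthase TYMS at -0.67 ± 0.408. Rows on the opposite strand went the other way for GAPDH (-0.20 ± 0.546), SLC16A3 (-0.42 ± 1.13), SLC1A5 (-1.12 ± 0.509) and TYMS (0.58 ± 0.669). The row opposite to PPAT went the same way (0.69 ± 0.633). The GAPDH and SLC1A5 rows held 199 and 73 counts in all libraries, against 73477 and 2685 opposite to them.

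The other metabolic lists had under 5 tested members and no set test. The nuclear-encoded respiratory chain had 4 of 54 tested, with a median log2 fold change of -0.24, and the TCA cycle 4 of 21, with a median of 0.15. Fatty acid synthesis had 4 of 14 tested (median 0.22), cholesterol synthesis 4 of 19 (median 0.31) and the pentose phosphate pathway 2 of 7 (median -0.15). FADS1, a fatty acid desaturase, had 0.73 ± 0.634 (SE).

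No epithelial or mucin gene passed the test. The pan-epithelial list had 4 of 16 members tested, all below 0 in LAMN libraries, with a median log2 fold change of -1.12. CLDN4, a tight junction claudin, had -1.67 ± 0.851 (SE), ELF3 -1.32 ± 1.24, and the rows of the keratins KRT8 and KRT18 -0.93 ± 0.665 and -0.52 ± 0.518. These keratin rows overlap by 525 bp on opposite strands and held 14769 and 323 counts in all libraries. The KRT8 row may therefore hold counts of KRT18, and the KRT18 row counts of KRT8. The median was -0.52 without CRC replicate 4 and -1.91 without LAMN replicate 3, where ELF3 had -0.18 and -2.57. CLDN4 had -0.79 without CRC replicate 1, and KRT8 -1.88 without LAMN replicate 3. In the goblet cell list 2 of 22 were tested, the membrane mucin MUC12 at -1.21 ± 0.528 and SPINK4 at 0.62 ± 0.730. In the gastric-type mucin list 2 of 12 were tested, CLDN18 at -0.96 ± 0.529 and the secreted mucin MUC5B at -0.44 ± 0.509. The intestinal identity list had 3 of 18 tested (median -0.32), mucin glycosylation 3 of 21 (median -0.06) and the absorptive colonocyte list 2 of 15 (median -0.39).

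Stromal and signalling lists gave the following values, with no member past the threshold. Extracellular matrix had 19 of 26 members tested, 9 above and 10 below 0, with a median log2 fold change of -0.02 (camera adjusted p = 0.478). DCN, the proteoglycan decorin, had 1.38 ± 0.810 (SE), with 2.14 without CRC replicate 2 and 0.76 without LAMN replicate 4. CTHRC1 had -1.10 ± 0.598. Immediate early genes, which respond to tissue handling as well as to signals, had 8 of 15 tested (median -0.32, camera adjusted p = 0.413), with JUNB at -1.56 ± 0.638. IER2 had 3 counts in all LAMN libraries, from LAMN replicate 2 alone, and 65 in CRC libraries, a log2 ratio of -3.28 (95% Clopper-Pearson interval -5.59 to -1.67). The hypoxia response had 8 of 16 tested (median -0.29, camera adjusted p = 0.972), with KDM3A at 1.36 ± 0.557 and VEGFA at -0.72 ± 0.719. Medians were 0.09 for proliferation (4 of 24 tested), 0.24 for Wnt targets (2 of 15), -0.21 for MAPK targets (3 of 16), -0.23 for the interferon response (4 of 20) and 0.33 for antigen presentation (3 of 18). The cAMP response had 0 of 11 members tested.

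No marker of another cell type passed over all genes. Smooth muscle had 7 of 12 tested (median 0.27, camera adjusted p = 0.540), with TAGLN at -0.76 ± 0.460 (SE). The TAGLN row held 327 counts in all libraries, and PCSK7, on the opposite strand, held 18414 and had 0.31 ± 0.503. PECAM1, a marker of endothelium, had -3.73 ± 1.18 and was 1 of 2 endothelial genes tested (median -2.09). It passed when adjusted over the list alone (edgeR adjusted p = 0.0182) and not over all genes (adjusted p = 0.997). CRC replicate 3 held 437 of its counts and the other CRC libraries 20 to 34, and without that library its log2 fold change was -1.42. Medians were 0.11 for fibroblasts (2 of 15 tested), 0.36 for mesothelium (3 of 12), 0.08 for adipocytes (2 of 15), 0.12 for T cells (2 of 16), -1.05 for macrophages (2 of 15) and 0.31 for neutrophils (1 of 11). They were -0.51 for hepatocytes (2 of 14), 0.34 for skeletal muscle (2 of 14), -0.41 for ovary (2 of 13), 0.18 for nerve (2 of 10), -0.34 for erythroid cells (1 of 8) and -0.20 for enteroendocrine cells (1 of 11). B and plasma cells and mast cells had 0 members tested.

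In all 8 libraries, rows of ubiquitously expressed genes held few counts while rows that overlap them on the opposite strand held many. ACTB, the cytoskeletal actin, had 230 counts in all libraries together. MALAT1, an abundant nuclear RNA (chromosome 11, 65497688 to 65506516, plus strand), had 3063 counts and TALAM1, its antisense transcript, 4389504. The ferritin gene FTH1 had 226 and BEST1 on the other strand 152930. The selenoprotein gene SELENOP had 97 and the overlapping CCDC152 37954. THBS2 and ACTA2 had 187 and 241 counts, against 75196 for THBS2-AS1 and 19824 for ACTA2-AS1. For GAPDH the opposite row held 369-fold more counts, for TPT1 379-fold, for VIM 280-fold and for TUBA1B 456-fold. EEF1A1 and ENO1 were exceptions, with 830 and 33 counts against 10 and 12 on their antisense rows. Among 2828 pairs of a coding gene and an antisense RNA with at least 50 counts, the antisense row had more counts per exonic kilobase in 2466, or 87.2% (95% Clopper-Pearson interval 85.9% to 88.4%), and in 80.7% to 86.5% within single libraries. A fold change of a gene row is therefore a value of that row, which need not be the abundance of the gene's own transcript. The same holds for the MT-RNR1 and MT-RNR2 rows, on the plus strand, whose counts may be antisense to the ribosomal RNA.

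**Figure D3:**
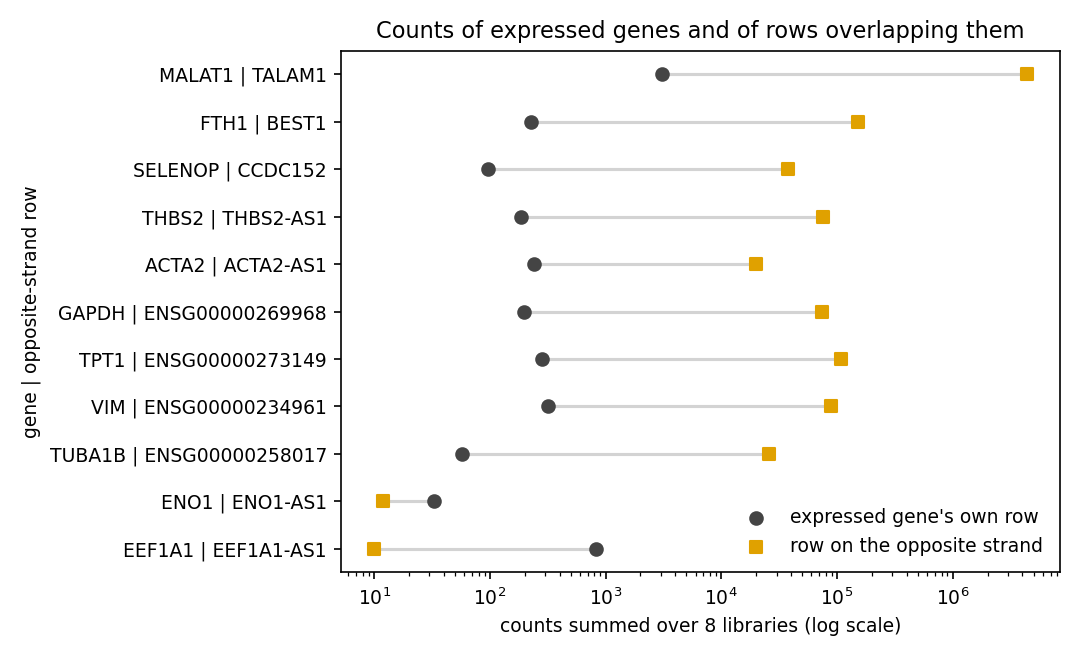
Counts summed over the 8 libraries (log scale) in the row of an expressed gene (circles) and in the row that overlaps it on the opposite strand (squares). The opposite row holds more counts in 9 of the 11 pairs drawn, as for FTH1 with 226 counts against 152930 for BEST1, and fewer for ENO1 and EEF1A1.

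The authors' deposited table listed 620 genes, 198 with a positive and 422 with a negative log2 fold change. By p, its leading negative genes in the authors' deposited table included USP37 at -5.82, GRTP1-AS1 at -5.80 and HOXB-AS3 at -4.49. USP37 overlaps VIL1, the gene of the brush border protein villin. Its leading positive genes included ENSG00000278456 at 4.09, ENSG00000203335 at 5.85, PUS10 at 2.10 and GFM1 at 2.67 in the authors' deposited table. The listed genes in it included the epithelial genes ELF3 at -3.29, SPINT1 at -4.26 and TSPAN8 at -5.99, the mitotic kinase gene PLK1 at -4.17 and the mesothelial and urothelial gene UPK1B at 2.36. It also held MT-CO1 at -2.05, MT-CO2 at -2.03, MT-ND1 at -2.36 and MT-ND2 at -2.04, which is 4 of the 13 mitochondrial chain genes (Fisher's exact adjusted p = 0.0143). Fisher's test takes genes as independent, but the estimated correlation between the 13 was 0.858, so this p overstates the evidence.

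These deposited fold changes did not follow the labels of the count columns. Of the 405 deposited genes tested here, 202 had the same sign as LAMN minus CRC and 203 the opposite sign, which is 49.9% alike. With edgeR 0 of them passed, 15 had an unadjusted p under 0.05, and DESeq2 called 0. Across genes, which are not independent replicates, Spearman's rho was -0.05 with edgeR and -0.09 with DESeq2. MT-RNR1 and MT-RNR2 were not among the 620. Which group a positive sign in the authors' deposited table stands for could therefore not be read from the labels. Except for the signs quoted from that table, every direction given above is that of the libraries labelled LAMN against those labelled CRC.

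**Figure D4:**
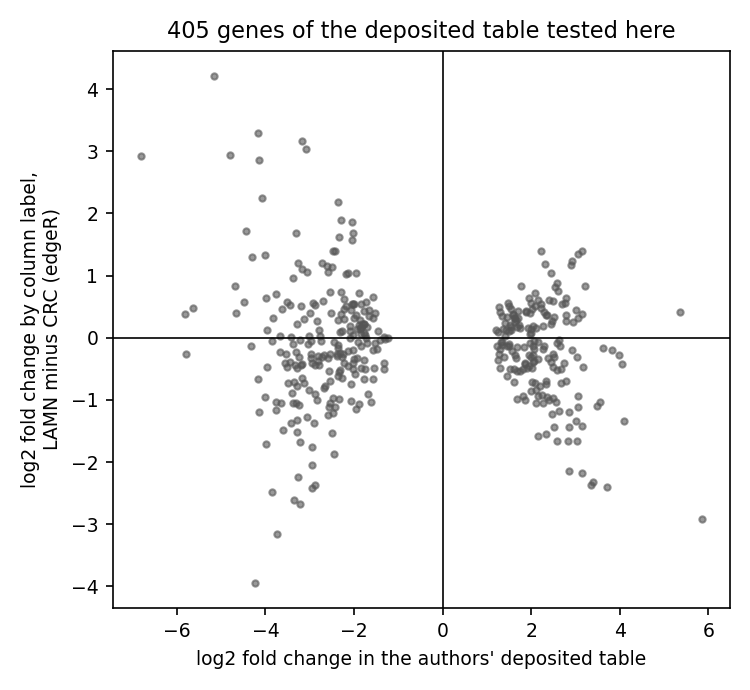
Log2 fold change of 405 genes in the authors' deposited table (horizontal) against the log2 fold change between the labelled groups, LAMN minus CRC, from edgeR (vertical), with 1 point per gene. The signs match for 202 genes and differ for 203.

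The main axes of variation among libraries did not separate the labels. The first principal component held 46.8% of the variance (exact permutation p = 0.914) and the second 18.4% (exact permutation p = 0.429). The third, with 12.6%, separated the labels (exact permutation p = 0.0286, adjusted p = 0.0444). TALAM1 took 35.5% ± 6.34 of the counts outside mitochondrial ribosomal RNA in LAMN libraries and 38.2% ± 6.17 in CRC libraries (SD, n = 4; exact permutation p = 0.543). The 50 highest genes took 91.2% ± 5.71 of all counts in LAMN and 51.3% ± 5.60 in CRC libraries (exact permutation p = 0.0286, the smallest the design allows). Counts outside mitochondrial ribosomal RNA averaged 852125 in LAMN and 2058970 in CRC libraries (exact permutation p = 0.0286).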

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

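The comparison of the DESeq2 fold changes with the deposited table was set beforehand. Its use to weigh an explanation, like the other tests of explanations in this part, was chosen after the results were seen. Single libraries far from the other 3 of their label were sought in 61 values, or 122 groups of 4 libraries. The values called others below are those of these 3 libraries only. For normally distributed values chance alone gives about 6.1 such libraries, and there were 18. The CPM values were not log-transformed. The 34 opposite-strand rows among the values were those with the most counts in their list, a choice that favours rows raised by a single library. Whether 18 exceeds chance can therefore not be read from this comparison. Many of the rows below overlap a gene on the opposite strand, and these are given as CPM of the counts outside mitochondrial ribosomal RNA, without TMM factors.

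Rows opposite to tissue genes stood out in CRC replicate 1. TTN-AS1, opposite to the titin gene TTN of striated muscle, had 25613 (others 26.6 to 586), APOA1-AS, opposite to the liver and gut apolipoprotein gene APOA1, had 2721 (others 18.1 to 37.1), and MRPS35-DT, opposite to the goblet cell gene REP15, had 418 (others 4.41 to 18.3). MUC5B-AS1, opposite to the mucin gene MUC5B, had 668 (others 0 to 63.3). TALAM1 took 28.9% of the counts outside mitochondrial ribosomal RNA there, against 40.6% to 41.8% in the other CRC libraries.

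LAMN replicate 3 had high values for ENSG00000257764, opposite to the lysozyme gene LYZ (5539; others 876 to 1250), the KRT8 row, which overlaps KRT18 (2181; others 365 to 463), and MUC5B-AS1 (643; others 28.6 to 78.8). ENSG00000285600, opposite to the replication gene MCM2, had 229.6 (others 34.2 to 41.4) and ENSG00000205414, opposite to the Wnt target NKD1, had 173.9 (others 10.5 to 20.3). The rows of 18 ubiquitous genes had 707 (others 274 to 323), and the first principal component was 55.9 (others -19.0 to -14.1). CRC libraries reached like values for the KRT8 row (2156 in CRC replicate 4) and MUC5B-AS1 (668 in CRC replicate 1). Their highest values were lower for ENSG00000257764 (1285), ENSG00000285600 (134) and ENSG00000205414 (122). The same held for the ubiquitous genes (299) and the first principal component (35.5).

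In other libraries, ADIPOQ-AS1, opposite to the adipocyte gene ADIPOQ, had 2683 in LAMN replicate 1 (others 3.38 to 235), and CLMAT3, opposite to the matrix gene SPARC, had 2156 in LAMN replicate 4 (others 314 to 604). The highest CRC value was 504 for ADIPOQ-AS1 (CRC replicate 4) and 3533 for CLMAT3 (CRC replicate 3). ENSG00000205414 had 122.1 in CRC replicate 4 (others 18.2 to 27.1), and SMARCB1, opposite to the plasma cell gene DERL3, had 135.5 in CRC replicate 2 (others at 11 or below). NAV2-AS2 had a CPM of 128 in CRC replicate 3 (others 49.5 to 58.4), and SIPA1 a CPM of 0.270 in LAMN replicate 1 (others 0). This last value is 1 count against 0 and carries no information on that library.

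For the mitochondrial ribosomal RNA of the libraries labelled LAMN, more mitochondrial transcripts of every kind was examined in the messenger RNA rows. The highest of these, MT-ATP8, had a log2 fold change of 2.35 against 8.54 for MT-RNR2. Because those rows may lie opposite to the RNA counted, the light-strand rows, which would then hold heavy-strand RNA, were examined too. MT-ND6 had 1.16 and 8 transfer RNA rows -0.38 to 2.35. If counts lie on the opposite strand, no row examined would hold the plus-strand messenger RNAs themselves. The test therefore cannot decide on this explanation. It shows only that these rows had smaller changes than the ribosomal RNA rows. Loss of strand marking would have raised the rows of ubiquitous genes, whose highest LAMN library exceeded the lowest CRC library by a log2 ratio of 1.97. The lowest LAMN share was 28.9-fold the highest CRC share, and removal of ribosomal RNA or library preparation that differed with the group may have caused this. It cannot be told apart from a difference between the tumours, because no label gives a batch. ENSG00000289474 and ENSG00000289901 may hold reads shared with these genes. Their ratios to the mitochondrial ribosomal RNA counts differed between the groups by 1.04-fold and 1.86-fold. The second ratio is uncertain, as ENSG00000289901 had 12 counts in CRC libraries, 8 of them in CRC replicate 1.

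For the counts opposite to expressed genes, reads without a strand would give a median log2 ratio near 0, and the ratio of antisense to coding rows was 5.28. Counting on the strand opposite to the transcripts is a candidate explanation, as 87.2% of the pairs had more counts on the antisense row. The rows of 18 ubiquitous genes, such as B2M with 32 and ACTB with 230, held at most 830 counts each over all libraries. The 8 mitochondrial transfer RNA rows of light-strand genes had a median of 1176 counts and the 14 of heavy-strand genes 0.5. No biological explanation was tested, and EEF1A1 and ENO1 were exceptions. For ENO1 both rows held few counts (33 and 12 on the antisense row), so this pair says little about the strand counted.

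For the deposited fold changes, another test tool was argued against by DESeq2, which with the labelled groups gave a Spearman correlation of -0.0945. Other libraries behind the table were argued against by a median ratio of 0.997 between the mean counts here and in the table. Group labels that differ between the table and the count columns may be the cause. In 1 of the 35 splits, 2 libraries of each group lay on the other side. Its DESeq2 fold changes had a Pearson correlation of 0.999994 to the table. Their median absolute difference from the table was 0.0252, against 2.74 with the labelled groups. These values argue against the labelled groups as those compared in the table. USP37, its leading negative gene, held 241 and 267 counts in CRC replicates 1 and 4. It held 30 and 151 in LAMN replicates 2 and 3, and 1 to 5 in the other libraries. Which of the 2 sets of labels is right stays open, and a difference between the tumours could not be read from the table by label.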

How the results depend on the processing

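Leaving out the mitochondrial ribosomal RNA rows, leaving out LAMN replicates 2 and 3 together and testing opposite-strand rows were chosen after the results were seen. The edgeR test called 4 genes. It called 7293 with library sizes as the only scaling (4 higher in LAMN, 7289 lower), when the median of all genes moved by -2.45. It called 72 with no low-count filter (25 higher, 47 lower, 2 of them among the 4), 2 when not robust and 2 without the mitochondrial ribosomal RNA rows. Leaving out each library in turn gave 1 to 4 genes, with 1 without CRC replicate 3, 2 without CRC replicate 1 and 2 without CRC replicate 2. MT-RNR1 and MT-RNR2 lost the call in these 3 cases, when not robust, and with no filter (adjusted p = 0.0581 and 0.0640).

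The camera test called 1 list, and 0 with an estimated correlation, with fry or on opposite-strand rows. It called 2 without the mitochondrial ribosomal RNA rows, and 1 to 2 when each library was left out in turn. The added lists were pan-epithelial, lower without CRC replicate 2 (adjusted p = 0.00506) and without LAMN replicate 3 (0.00829), immediate early genes, lower without LAMN replicate 1 (0.0333) and LAMN replicate 2 (0.0304), and extracellular matrix, lower without LAMN replicate 4 (0.0248). Without the mitochondrial ribosomal RNA rows the added list was immediate early genes, lower (0.0326), and without LAMN replicates 2 and 3 together pan-epithelial was the only list called, lower (0.0476).

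The median of the mitochondrially encoded respiratory chain stayed 1.57 with an estimated correlation (adjusted p = 0.705) and fry (adjusted p = 0.626), where only the test changes. It was -1.54 with library sizes as the only scaling, above the -2.48 of all genes, so camera still placed the list higher (adjusted p = 5.55e-05). It was 0.16 without LAMN replicates 2 and 3 (adjusted p = 0.750). With library sizes alone ENSG00000291075 was -0.16 and OLFML1 -0.36, and 8 of the 16 named genes, all lower, gained a call. Under the remaining alternatives 287 values of named genes had the same verdict, 15 lost a call and 5 gained one. With all tested genes the first principal component held 37.2%.

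With the replicate number as a block 0 genes passed with edgeR, while the log2 fold changes were 8.39 for ENSG00000289474, 9.34 for ENSG00000289901, 8.75 for MT-RNR1 and 8.28 for MT-RNR2. The numbers did not pair the libraries, as 0 of 4 LAMN libraries correlated best with the CRC library of their number.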

Other observations

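Only the 2 counts over other splits of the libraries were set before their results were seen; the other tests in this part were chosen after. Rows opposite to listed genes gave a second view of the tissue, because the antisense row held more counts in 87.2% of the pairs examined. None of these rows passed over all genes by label, and 0 lists passed with camera. The smooth muscle rows had 12 tested and a median log2 fold change of 0.40 (camera adjusted p = 0.0541). With an estimated correlation the camera adjusted p was 0.903, and fry gave an unadjusted p of 0.349. NDE1, ENSG00000263065 and ENSG00000263335, all opposite to MYH11, had 2.64, 2.40 and 2.49, and 0.09, -0.12 and 0.26 without LAMN replicate 3. ACTA2-AS1, opposite to the smooth muscle actin gene ACTA2, ran from a CPM of 590 to 4172 of the counts outside mitochondrial ribosomal RNA. The 8 tested skeletal muscle rows, 7 of them opposite to TTN alone, had a median of -4.09 (camera adjusted p = 0.734). This came from CRC replicate 1, which held 53558 of the 56849 counts of TTN-AS1, and without that library the median was 0.86. PHLDA1-AS1, opposite to a MAPK target, ran from 157 to 302 in LAMN and 381 to 714 in CRC libraries. It passed when adjusted over its list alone (edgeR adjusted p = 0.00853) but not over all genes. The hepatocyte and goblet cell rows had 2 tested each, with medians of -5.15 and -2.29, which were -1.19 and -0.60 without CRC replicate 1. With all libraries each of these lists also had a row past the threshold when adjusted over the list alone (lowest edgeR adjusted p 0.00982 and 0.0379).

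Epithelial rows, pooled after the results were seen, were more often among the negative genes of the authors' deposited table than other rows were. Of 51 epithelial rows, members and opposite-strand rows together, 10 were negative in the table, or 19.6% against 3.05% of the 13514 others (Fisher's exact p = 3.11e-06). The test takes rows as independent, but rows of the same libraries can overlap or vary together, so its p may overstate the evidence. Tested list by list none of the epithelial lists passed, with the lowest adjusted p for the pan-epithelial members (Fisher's exact adjusted p = 0.322) and the rows opposite to them (0.110). The odds ratio was 7.75, and a difference in epithelial transcripts between the 2 sets of libraries behind the table may be its source. The rows included ELF3 at -3.29, SPINT1 at -4.26, TSPAN8 at -5.99 and MUC5B-AS1 at -3.42 in the authors' deposited table, and rows opposite to CDH1 at -2.06 and GRHL2 at -4.15. None of the 51 was positive there (0 of 51; Fisher's exact p = 1). As the table does not follow the column labels, this difference was not assigned to a tumour type.

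Chance could not be excluded for the number of genes called between the labelled groups. With edgeR they numbered 4, the highest of the other splits also gave 4, and 2 of the 35 splits gave as many. DESeq2 called 6 genes between the labelled groups and 596 in the split that matched the deposited table. That split was picked for its match to a table that holds only genes past the threshold. A high DESeq2 count there was thus fixed in advance and shows no structure of the libraries. With edgeR that split, like all others, gave at most 4 genes. DESeq2 was not run on the remaining splits. The number of genes called takes no account of the size of a difference. The shares of mitochondrial ribosomal RNA, 69.2% to 93.5% against 0.717% to 2.39%, did not overlap (exact permutation p = 0.0286, the smallest possible here). Chance could not be excluded for the number of lists either, where the labelled groups gave 1, the highest other split 3, and 24 of the 35 splits gave as many.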
